A study of Mus musculus with 6 samples.

How the data were processed

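The series holds 6 arrays of RNA from mouse bone marrow-derived macrophages, with 1 array for each of 2 genotypes (Dicer WT and Dicer KO) and 3 RNA fractions (input, AGO2-RIP and IgG-RIP). Per the labels, the mice were male, which the sex-linked transcripts of the WT arrays contradict, and carried LysM-Cre and an inactivated Apoe, and the bone marrow cells were grown in medium with L929-conditioned supernatant. Per the labels' protocols, detergent lysates were cleared by centrifugation, input RNA was taken from the supernatant, and magnetic beads that carried IgG or a monoclonal mouse antibody to AGO2 were incubated with the extract for 7 hours. RNA was reverse-transcribed and pre-amplified, and 500 ng of cDNA per sample was cut with Alu I and Rsa I and labelled with Cy3 by random priming. Pre-amplification and random-primed labelling can weight transcripts unequally, and equal cDNA mass on every array hides any difference in the amount of RNA precipitated, so all comparisons are of relative abundance. Which samples shared a cell preparation is not given in the sources used here.

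The deposited files are Agilent Feature Extraction output, version 10.7.3.1 per the submitters' processing notes and the file headers, for 1-colour arrays of 60-base probes annotated on mm9. Per the file headers, the processed signal is an intensity in linear units from which the background was subtracted and spatial trends were removed, and in which dim spots carry a surrogate value. It was not normalized between arrays. Per the file headers, the arrays also carry flags for spots well above background, saturated spots and outliers. The 6 arrays lay on 1 slide with 1 scan, KO on slide row 1 and WT on slide row 2, so genotype and slide row cannot be told apart and no batch could be tested. No spot was saturated (0 on each array). Median signals ran from 7.99 (WT input) to 15.4 (KO AGO2-RIP), and negative controls had medians of 3.89 to 4.51.

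The main values were log2 of the processed intensity minus the array's 75th percentile over the 59305 non-control spots. Spots of the same probe were averaged, 54 probes with an outlier spot were left out, and a gene was represented by its probe with the highest mean signal, of 55627 probes kept. Gene names were taken from the files and updated through a RefSeq gene table (assembly GRCm38.p6, used for names only). Of the probes, 27656 were matched by accession, 3401 by symbol and 321 by synonym, and 24303 kept the name on the array. Coordinates are those of the array files. Paralogs with similar sequences, such as histone genes, ribosomal protein genes and the lysozymes, can share a probe's signal.

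A gene was measured in a comparison where it was well above background on every array of it. Where 1 array was dim, the bound was the bright value minus the higher of the dim probe's own value and the lowest spot well above background on the dim array, and it counted where it reached the fold threshold of 2. Differences of differences (WT minus KO of AGO2-RIP over IgG-RIP or over input) were taken over genes measured on all 4 arrays. Each is a plain difference with no test. Where a gene had a measured second probe, that probe was past 2-fold the same way for 49.2% of the genes past 2-fold over IgG-RIP in WT, 33.9% in KO, 45.1% for the WT minus KO difference, 40.3% for that over input and 42.1% for KO minus WT input.

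For each of 31 lists, covering miRNA machinery and targets, metabolism, immune activation, the cell cycle, ribosomal proteins, nuclear RNAs and cell types, the median of its measured members was placed among 10000 random lists of the same size, drawn within 20 bins of mean signal, and given as a percentile. Lists with fewer than 5 measured members have no median. The named genes are the 8 highest and 8 lowest measured genes with an assigned symbol in each comparison, the genes Dicer1, Ago2, Lcor and Apoe, and the 2 highest and 2 lowest members of a list that is described, or fewer, and 1 list member is not reported here. The comparisons, lists, naming rule and alternative settings were chosen before the data were examined.

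The precipitation over both genotypes was tested with limma 3.58.1 (lmFit and eBayes, fraction plus genotype, two-sided, Benjamini-Hochberg adjustment) in R 4.3.3 on 18888 genes above background on at least 2 arrays. The genotype by fraction interaction serves as its error, so a gene whose enrichment depends on Dicer tends not to be called. Whether the samples of a group come from separate animals is not given in the sources used here. Other steps used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1.

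The procedures were tested on simulated data. With the spot noise of the WT AGO2-RIP and IgG-RIP arrays (15216 genes), 2% of genes changed by 1.5-fold, 56% of those changed by 2-fold and 100% of those changed by 3-fold or 4-fold passed the 2-fold threshold, and 0 unchanged genes did. That noise, 0.22 log2 for the difference, leaves out culture, precipitation and amplification. Probes of the same gene varied by an SD of 0.89 in the real comparison. The 0 thus does not bound how many unchanged genes pass 2-fold in the data. In the same comparison 8% of 200 random lists of 20 genes fell outside the percentiles 2.5 to 97.5, and 74% of lists shifted by 1 log2 lay above 97.5. For limma on 18888 genes, 0 of the 50 genes simulated at each of 2-fold, 4-fold, 8-fold and 16-fold were called, with mean estimates of 0.98 to 1.06 times the true value.

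Alternatives were quantile normalization, centring each array on the median of the genes above background on all 6 arrays, normexp background correction (offset 50) of the mean and background intensity that the authors deposited, the median of a gene's probes, only genes above background on all 6 arrays, and no filter. For limma they also were the 4 precipitate arrays alone, leaving out each of these in turn, and no genotype term. The search for miRNA seed sites in 3' untranslated regions was planned for 30 seed families and was not run, since it needs a genome sequence that was not used here.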

Results

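Bone marrow-derived macrophages were grown from mice that carried LysM-Cre, which drives Cre recombinase in myeloid cells, on an Apoe-deficient background. Dicer WT cells had unfloxed Dicer alleles and Dicer KO cells had floxed ones, so that the KO cells were to lack Dicer, the enzyme that cuts miRNA precursors. From each genotype, RNA was taken before precipitation (input), after precipitation with an antibody to AGO2, the Argonaute protein that carries miRNAs to their target transcripts (AGO2-RIP), and after precipitation with control IgG (IgG-RIP). Each of the 6 RNAs was hybridised to 1 Cy3 array, giving 1 array per group. Between 37.6% (WT input) and 46.3% (KO AGO2-RIP) of the 59305 non-control spots lay well above background, with 44.6% on the WT AGO2-RIP, 42.3% on the WT IgG-RIP, 41.0% on the KO input and 42.2% on the KO IgG-RIP array. Of 34755 genes, 12385 were above background on all 6 arrays. The input arrays correlated most closely across these genes (Pearson r = 0.987), followed by the AGO2-RIP arrays (0.95) and the IgG-RIP arrays (0.925). Within a genotype, AGO2-RIP and IgG-RIP correlated at 0.834 in WT and at 0.924 in KO. Genes are not independent replicates, so these correlations describe the arrays only.

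With 1 array per group no difference between groups had a replicate check, and no p-value is given across genes. Spots of the same probe, printed 10 times on each array, had a root mean square SD of 0.14 to 0.17 log2, which leaves out culture, precipitation and amplification. The labels give male mice for all 6 samples, but Xist, transcribed from the inactive X chromosome of female cells, was well above background on 3 of 3 WT arrays (0.14 in input, 3.92 in AGO2-RIP and 5.70 in IgG-RIP) and on 0 of 3 KO arrays. The Y-linked genes Ddx3y (0.95, 1.81 and 0.51) and Eif2s3y (0.01, -0.63 and 0.14) were above background on 3 of 3 KO arrays and on 0 of 3 WT arrays, while Uty was so on 2 KO arrays, Kdm5d on 0 arrays and Sry on all 6. These genes were chosen after their values were seen. The sex of the cells thus went with genotype, and every KO and WT difference below could come from either. Values below are log2 differences of signal scaled to each array's 75th percentile, "at least" marks a bound against a dim spot, and "2-fold" is a size and not a test.

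Dicer1 was measured by 1 probe (mm9 chromosome 12, 105926064 to 105926123). Its signal was -0.55 on the KO input and 0.22 on the WT input array, a KO minus WT difference of -0.77 or 1.71-fold. It was 0.94 on the KO and 0.93 on the WT AGO2-RIP array, a difference of 0.01, and it was not well above background on the KO IgG-RIP array, where WT gave 0.18. The labels do not give the floxed exons, so the probe may lie outside the deleted part and checks neither the deletion nor the labels. Ago2 was higher in KO input by 0.81, and its probe with the brightest signal gave AGO2-RIP minus IgG-RIP differences of -0.52 in WT and -0.35 in KO, while another of its 3 probes gave 0.29 and 0.51. Apoe, the gene inactivated in both genotypes, still gave signal, with a KO minus WT input difference of -0.18 and AGO2-RIP minus IgG-RIP differences of -1.38 in WT and -1.98 in KO. Lcor, which encodes a ligand-dependent nuclear receptor corepressor, was 2.40 higher in KO input (5.28-fold). Its AGO2-RIP signal was 2.94 above IgG-RIP in WT and 0.60 above it in KO.

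**Figure D1:**
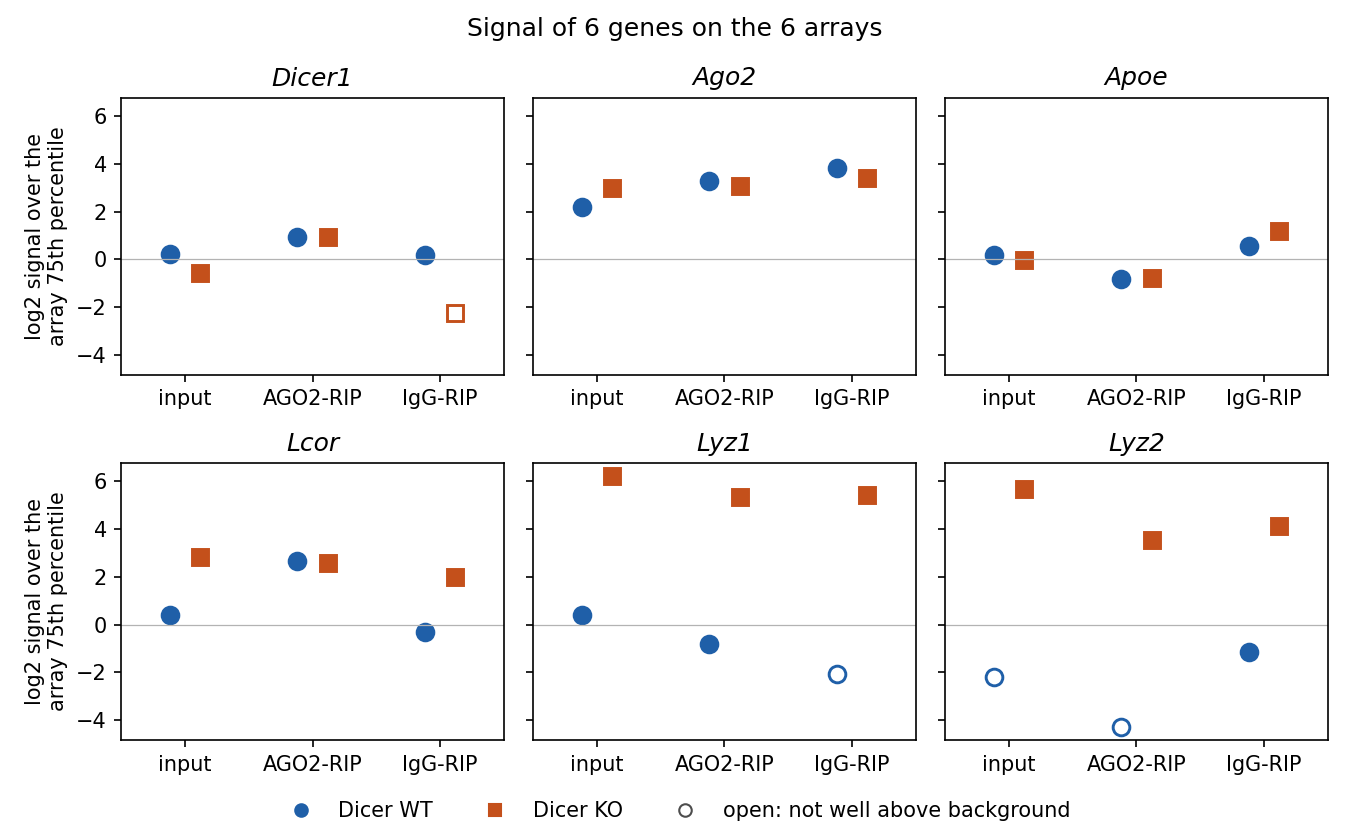
Signal of Dicer1, Ago2, Apoe, Lcor, Lyz1 and Lyz2 on each of the 6 arrays, as log2 of the signal over the array's 75th percentile on the vertical axis and the RNA fraction on the horizontal axis. Circles are Dicer WT, squares are Dicer KO and open symbols are spots not well above background. The Lcor signals of WT and KO were 0.42 and 2.82 in input and 2.65 and 2.59 in AGO2-RIP.

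The input arrays address what loss of Dicer did to RNA levels. The highest genes in KO input were Lyz1 (5.81), a lysozyme, Lcor (2.40), the transcription factor gene Atf7 (2.31), Tmem176b (2.28) and Rsad2 (2.23), which encodes the antiviral protein viperin. They were followed by the integrin subunit gene Itgb3 (1.82), the presynaptic scaffold gene Bsn (1.78) and the hyaluronidase gene Hyal1 (1.76). The lowest were Slc32a1 (-5.22), a vesicular transporter of inhibitory amino acids, Dnmt3l (-2.47), a cofactor of DNA methyltransferases, Prg4 (-2.41), which encodes lubricin, the pseudouridine synthase gene Pus7 (-2.34), the keratin gene Krt7 (-2.31), Mtap (-2.30), Tmsb15b1 (-2.26) and the glutathione transferase gene Gsta3 (-2.22). Another measured probe gave the opposite sign for Atf7, Slc32a1 and Tmsb15b1. The Slc32a1 signal was high on the WT input array alone (4.83, against at most 0.92 on the other arrays). In total 227 genes were at least 2-fold higher and 493 at least 2-fold lower in KO, or 150 and 253 among the 14664 genes above background on both arrays. With normexp the counts fell to 51 higher and 92 lower. With only the genes above background on all 6 arrays the share of higher genes moved from 31.5% to 43.9%. The median of all genes was -0.08, and the SD across genes was 0.44.

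Let-7 targets stood higher in KO input, with a list median of 0.43, above all of 10000 random lists of the same size and signal (percentile 100). Of its 14 measured members 2 were at least 2-fold higher and 0 lower, with Arid3b (1.72) and Arid3a (1.20), both DNA-binding proteins, at the top and Hmga1 (-0.39) and Nras (-0.15) at the bottom. Interferon-stimulated genes had a median of 0.25 (percentile 99.5), with 4 of 19 at least 2-fold higher, led by Rsad2 (2.23) and Ifit3 (1.67). Stat2 (-0.04) and Bst2 (-0.01) were their lowest members. Genes of the miRNA machinery had a median of 0.15 (percentile 98.0), with Tnrc6a (1.33), a partner of Argonaute proteins, at the top and Dicer1 (-0.77) and Drosha (-0.20) at the bottom. The targets of miR-17~92 had a median of 0.17 (percentile 98.6), and none of the 10 differed by 2-fold. Macrophage lipid handling genes had a median of 0.06 (percentile 98.8), with the cholesterol exporter gene Abca1 (1.26) and the lipase gene Lpl (1.13) higher and the lipid chaperone gene Fabp4 (-1.56) and the lysosomal lipase gene Lipa (-0.58) lower. Cytosolic ribosomal protein genes had a median of -0.52 (percentile 0.00), and 0 of 75 differed by 2-fold, from Rps3 (-0.07) to Rpl12 (-0.85). Mitochondrial ribosomal protein genes had a median of -0.25 (percentile 0.01) but lay 0.08 above the median of all genes when no filter on dim genes was used. Nuclear non-coding RNAs had a median of -0.71 (percentile 0.00), with 3 of 11 at least 2-fold lower, among them Gas5 (-1.45) and Rnu2-10 (-1.40). Fatty acid oxidation genes (0.06, percentile 90.7) and miR-155 targets (-0.01, percentile 67.1) had 1 member past 2-fold between them, the miR-155 target Cebpb (-1.04). The percentiles describe these arrays and not the genotypes.

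AGO2-RIP over IgG-RIP in Dicer WT cells addresses which transcripts were held with AGO2. The highest genes were Dcakd (6.93), Ccdc28b (6.07), Tnfsf9 (5.94), a ligand of the tumour necrosis factor family, the zinc finger gene Zfp770 (5.74), the cytochrome oxidase subunit gene Cox7a1 (5.42), Ethe1 (5.38), a mitochondrial sulfur dioxygenase, Plcxd2 (5.38) and Ddit4 (5.33), a stress-induced inhibitor of mTOR. The lowest were the mucin gene Muc5b (-10.13), Rpp30 (-4.98), a protein of ribonuclease P, Tmem87a (-4.48), the kinase scaffold gene Mapk8ip3 (-4.46), Cracr2b (-4.29), Ifi27l2b (-4.22), D9Ertd115e (-4.21) and Zfp954 (-3.76). The Muc5b signal was high on the WT IgG-RIP array alone (7.91), and Tmem87a turned to 1.20 with the median of its probes. On the WT IgG-RIP array the dimmest spot well above background was at -2.03. Dcakd (-1.89) and Plcxd2 (-1.80) lay near it there, so their differences rest on dim control spots. Tnfsf9 (0.97) and Ddit4 (1.45) lay well above it. Relative to IgG-RIP, 4018 genes were at least 2-fold higher and 4599 at least 2-fold lower, or 3094 and 3384 of the 15216 measured on both arrays. The median of all genes was -0.24 and shifted to -0.51 with the arrays centred on the median, to -0.32 with quantile normalization and to -0.13 with normexp, and list medians below are read against the -0.24. The share of higher genes was 46.6%, against 33.8% with median centring (3261 higher, 6390 lower), 67.5% with normexp (2948 and 1420) and 56.9% with only genes above background on all arrays (2906 and 2198).

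Let-7 targets led the WT precipitate, with a median of 2.88 (percentile 100) and 10 of 14 members at least 2-fold higher, among them Arid3b (4.13) and the cell cycle phosphatase gene Cdc25a (3.82). Trim71 (-1.38) was its lowest member. The p53 targets had a median of 1.75 (percentile 99.99), with 13 of 17 at least 2-fold higher, led by Bbc3 (4.35), a mediator of apoptosis, and Cdkn1a (3.34), an inhibitor of cyclin-dependent kinases, with Polk (0.21) and Mdm2 (0.33) lowest. The miR-155 targets had a median of 1.14 (percentile 98.9), with 7 of 13 at least 2-fold higher, led by Bach1 (3.21) and Socs1 (2.17), though random lists matched on probe GC too put it at percentile 95.4. The miR-17~92 targets had a median of 1.07 (percentile 98.4), with Cdkn1a (3.34) and Bcl2l11 (2.65) at the top. Targets of miR-223 (0.75, percentile 92.6), miR-21 (0.33, percentile 91.7) and miR-10a (0.02, percentile 70.7) lay within the range of random lists. The miR-10a list holds Lcor, known from the study itself, and is no independent evidence. The 5 measured miR-146a targets had a median of -1.17 (percentile 1.68), with Relb (-2.36) and Numb (-1.70) lowest and Smad4 (1.94) highest, but stood 0.77 above the median of all genes with no filter. Bach1 stands in the let-7 and miR-155 lists and Cdkn1a in the p53 and miR-17~92 lists.

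Inflammatory genes were also high over IgG-RIP in WT, with a median of 1.04 (percentile 99.7) and 9 of 18 at least 2-fold higher, led by the chemokine genes Ccl3 (4.05) and Ccl7 (4.03), while Ccl5 (-1.83) and Cxcl2 (-1.55) were lowest. Interferon-stimulated genes had a median of 0.55 (percentile 97.3), just within the range of random lists, with Irf9 (4.48) and Ifit3 (3.38) highest. Mitochondrial ribosomal protein genes had a median of 0.86 (percentile 100), with 32 of 66 at least 2-fold higher, led by Mrpl53 (5.08) and Mrpl44 (3.87). Respiratory chain genes had a median of 0.86 (percentile 99.9), with 20 of 47 at least 2-fold higher, led by Ndufa4 (3.96) and Ndufs4 (3.73). Fatty acid oxidation genes had a median of 0.77 (percentile 99.6), with 11 of 25 at least 2-fold higher, among them the acyl-CoA dehydrogenase gene Acadl (3.81) and the acyl-CoA synthetase gene Acsl1 (3.66), and with Ppara (-1.55) and Acaa2 (-1.46) lowest. Cell cycle genes had a median of 0.68 (percentile 99.4), led by the cyclin genes Ccne1 (4.27) and Ccnb1 (2.87). The mitochondrial groups went the other way over input, where the respiratory chain median was -1.21 (percentile 0.38) and the mitochondrial ribosomal protein median -1.22 (percentile 0.00), and fatty acid oxidation genes lay within the range of random lists there (-0.31, percentile 40.6). Let-7 targets (1.90, percentile 100), p53 targets (0.65, percentile 99.1) and miR-223 targets (0.74, percentile 98.4) stood high over input. Inflammatory genes (0.21, percentile 94.2), interferon-stimulated genes (-0.04, percentile 60.4), cell cycle genes (-0.07, percentile 82.6) and the targets of miR-155 (0.37, percentile 92.9) and miR-17~92 (0.45, percentile 96.3) lay within the range of random lists over input.

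AGO2-RIP over IgG-RIP in Dicer KO cells was led by Ddit4 (7.97), Zc3hav1l (6.25), a relative of the zinc finger antiviral protein, Tnfsf9 (6.22) and Lfng (5.52), a glycosyltransferase that modifies Notch. Next came the tetraspanin gene Cd151 (5.20), Chac1 (4.84), a glutathione-degrading enzyme of the unfolded protein response, Sertad3 (4.79) and the nuclear receptor gene Esrra (4.71). On the KO IgG-RIP array the dimmest spot well above background was at -2.15. Chac1 (-2.04), Ddit4 (-1.85) and Esrra (-1.81) lay near it there, so their differences rest on dim control spots. Tnfsf9 (-0.53) and Cd151 (-0.88) lay further above it. The lowest genes were the adhesion molecule gene Clmp (-4.03), Cyb5rl (-3.96), Parp11 (-3.78), the sodium-calcium exchanger gene Slc8a1 (-3.53), Tulp3 (-3.52), Cyhr1 (-3.46), Nsun5 (-3.32) and Aldh4a1 (-3.32). Clmp moved to -2.22 and Cd151 to 3.82 with the median of their probes. Dicer1 itself was at least 8.48-fold higher in AGO2-RIP than in IgG-RIP in KO, against 1.69-fold in WT. In KO 2418 genes were at least 2-fold higher and 2125 at least 2-fold lower, or 1636 and 1552 of 15649 measured on both arrays. The share of higher genes was 53.2%, against 66.4% with normexp (1174 and 593), and the median of all genes was -0.19. The SD across genes was 0.88, against 1.32 in WT.

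Let-7 targets stood high in the KO precipitate as well, with a median of 0.97 (percentile 100) and 6 of 14 at least 2-fold higher, led by Cdc25a (2.30) and the chromatin protein gene Hmga2 (1.93), with Nras (-0.22) among the lowest. The p53 targets had a median of 0.81 (percentile 99.99), with 8 of 18 at least 2-fold higher, led by the antiproliferative gene Btg2 (3.84) and Bbc3 (3.59). The miR-21 targets had a median of 1.44 (percentile 100), with 4 of 7 at least 2-fold higher, led by Btg2 (3.84) and Smad7 (1.95), but stood at -0.05 relative to the median of all genes with only genes above background on all arrays. The miR-223 targets had a median of 0.63 (percentile 99.6) and the miR-155 targets of 0.43 (percentile 97.9, or 93.4 with random lists matched on probe GC too), while those of miR-17~92 (0.22, percentile 92.5), miR-146a (-0.26, percentile 39.9) and miR-10a (0.08, percentile 77.6) lay within the range of random lists. Inflammatory genes had a median of 0.64 (percentile 99.95), with Ccl7 (2.48) and the cytokine gene Tnf (2.43) highest. Mitochondrial ribosomal protein genes (0.19, percentile 99.7) and respiratory chain genes (0.19, percentile 99.8) had 10 of 66 and 5 of 47 members at least 2-fold higher, but stood low over KO input (-1.41 and -1.32, percentiles 0.00 and 0.22). Fatty acid oxidation genes had a median of 0.11 (percentile 94.1), with 4 of 26 at least 2-fold higher. Replication-dependent histone genes had a median of 0.11 (percentile 98.97), led by H3c11 (1.78) and H3c8 (1.56), but of -0.83 over KO input (percentile 7.12). Over KO input let-7 targets (1.04, percentile 99.98) and p53 targets (0.32, percentile 98.6) stood high, while inflammatory genes (percentile 90.1) and the targets of miR-21 (86.0), miR-223 (96.6) and miR-155 (82.8) lay within the range of random lists.

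**Figure D2:**
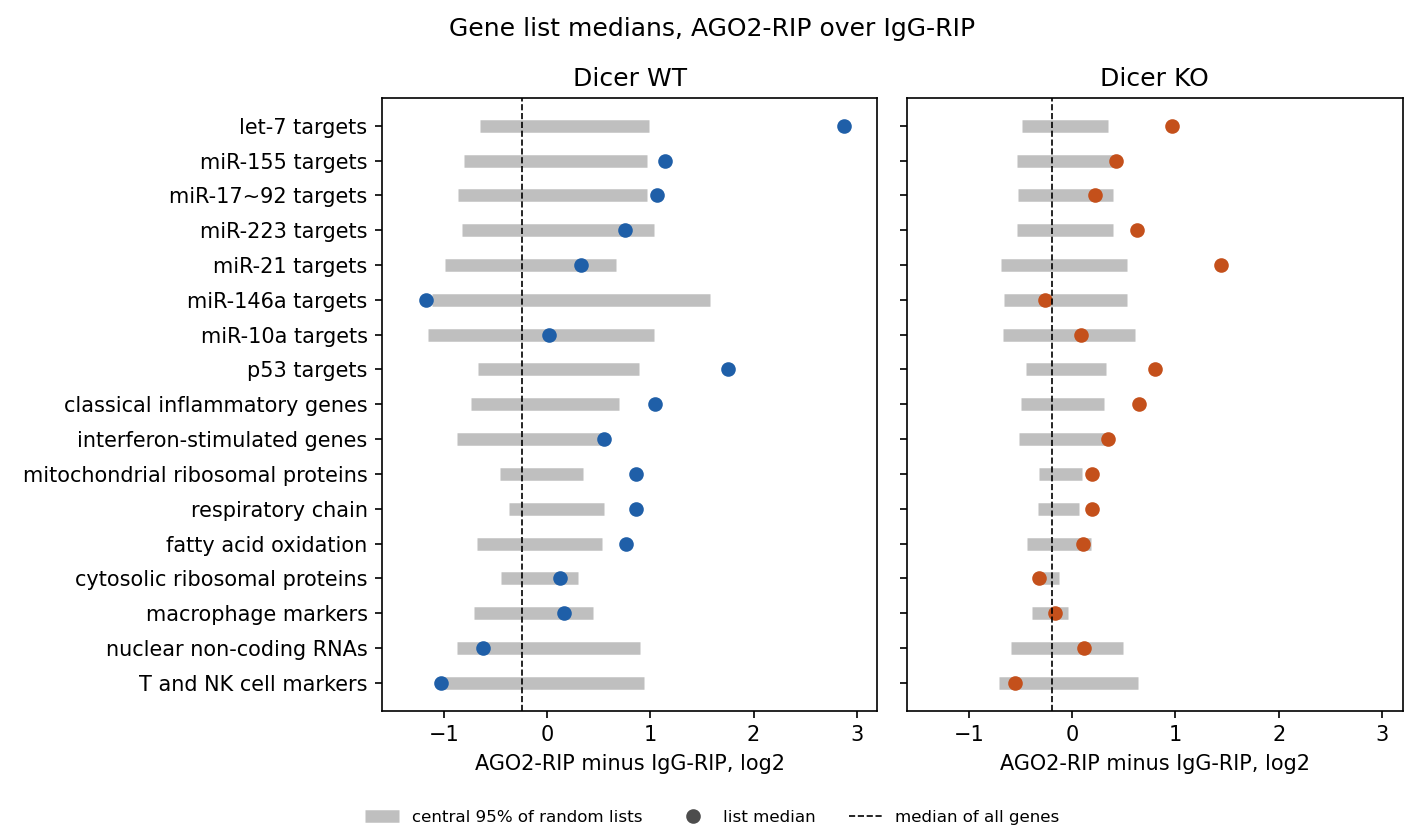
Medians of 17 gene lists in AGO2-RIP minus IgG-RIP (log2, horizontal axis), for Dicer WT and Dicer KO. Points are list medians, grey bars span the central 95% of 10000 random lists matched on signal, and the dashed line is the median of all genes. The let-7 median lay at 2.88 in WT and 0.97 in KO, outside the bar in both.

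Over 14054 genes measured on all 4 precipitate arrays, the WT and KO differences correlated at r = 0.45, and the SD across genes was 1.53 times as large in WT as in KO. Of these genes 888 were at least 2-fold higher over IgG-RIP in both genotypes, where independent lists would share 303, and 370 were at least 2-fold lower in both, where independent lists would share 276. Ddit4 and Tnfsf9 were among the 8 highest in both genotypes. The 2 differences share no array. Both fell with rising probe GC (Spearman rho -0.24 in WT and -0.20 in KO), and the numbers for independent lists were not adjusted for it.

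Treating the genotypes as replicates of the precipitation, limma with an additive fraction and genotype model on all 6 arrays (2 residual degrees of freedom) called 0 of 18888 genes higher and 0 lower in AGO2-RIP than in IgG-RIP at an adjusted p under 0.05. The smallest adjusted p was 0.0733, and at an unadjusted p under 0.05 limma gave 2299 genes higher and 1255 lower. With limma, 538 genes were called higher and 40 lower when only the 12385 genes above background on all arrays were tested, 248 and 15 with normexp, and 134 and 12 in a model with no genotype term (3 residual degrees of freedom). Without the KO IgG-RIP array limma called 459 higher and 67 lower, with 1 residual degree of freedom and a spread that came only from the input and AGO2-RIP arrays. In simulated data 0 of the genes changed by 16-fold were called, so the count of 0 does not bound how many genes differ. The simulation drew each gene's SD from the fitted residual SDs, which scatter more than true SDs, and changed few genes. It may thus be harsher than the data and does not measure how often limma misses a gene here.

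The WT minus KO difference of AGO2-RIP over IgG-RIP addresses which associations with AGO2 needed Dicer. The genes higher in WT were led by Kcna3 (6.26), a voltage-gated potassium channel, Wdtc1 (6.04), Fkbp2 (5.87), a prolyl isomerase of the endoplasmic reticulum, Vps8 (5.27), a tethering factor of endosomes, Bcs1l (4.94), an assembly factor of the respiratory chain, the phosphatase subunit gene Ppp2r5d (4.86), Angptl6 (4.63) and the transcription factor subunit gene Gtf2h2 (4.60). Those higher in KO were led by Muc5b (-9.67), D9Ertd115e (-6.65), the chemokine receptor gene Cxcr6 (-5.47), D10Bwg1070e (-5.13), Ica1 (-4.96), the vault protein gene Mvp (-4.72), Tent5a (-4.71) and Zfp108 (-4.71). On the WT IgG-RIP array Wdtc1 (-1.99), Ppp2r5d (-1.85) and Kcna3 (-1.77) lay near the dimmest spot well above background (-2.03). On the KO IgG-RIP array Zfp108 (-1.98) and Ica1 (-1.96) lay near the dimmest such spot (-2.15). These differences thus rest in part on dim control spots, while Fkbp2 (-0.73) and Gtf2h2 (0.09) lay further above it on WT IgG-RIP. Another measured probe gave the opposite sign for Ppp2r5d, Gtf2h2 and Tent5a. Lcor was 2.34 higher in WT, or 1.06 with the median of its probes, but its AGO2-RIP signals differed by -0.05 and its IgG-RIP signals by 2.29 (KO minus WT), so the difference came from the control. Of 14054 genes 2839 were at least 2-fold higher in WT and 2314 at least 2-fold higher in KO. The share higher in WT was 55.1%, against 39.0% with median centring (2101 and 3284), which moved the median of all genes from 0.03 to -0.23, and 65.1% with normexp (2011 and 1078). Of the 2839 genes, the AGO2-RIP arrays alone differed by at least 2-fold in 931 and the IgG-RIP arrays alone in 1276, and across genes the difference correlated with its AGO2-RIP part at 0.70 and with its IgG-RIP part at 0.79.

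Let-7 targets were again set apart, with a median WT minus KO difference of 1.54 (percentile 99.99) and 10 of 14 at least 2-fold higher in WT, led by Arid3b (3.19), while Hic2 (-1.62) and Trim71 (-1.27) were at least 2-fold higher in KO. Between the IgG-RIP arrays alone let-7 targets were 0.62 higher in KO (percentile 99.3), so part of the difference came from the control. The let-7 percentile of the WT minus KO difference was 84.9 once the KO values were stretched to the WT spread. The p53 targets had a median of 1.04 (percentile 99.5), with 9 of 17 at least 2-fold higher in WT and 0 in KO, led by the apoptosis gene Pmaip1 (2.08) and Ei24 (2.03), and the same stretch brought their percentile to 94.9. Mitochondrial ribosomal protein genes (0.79, percentile 100) had 25 of 62 at least 2-fold higher in WT, led by Mrpl21 (3.12) and Mrpl53 (2.88). In KO minus WT they stood at 0.33 between the IgG-RIP arrays alone (percentile 99.8) and at -0.48 between the AGO2-RIP arrays alone (percentile 0.08). Part of their difference thus came from the control. Respiratory chain genes (0.80, percentile 99.9) had 17 of 47 at least 2-fold higher in WT, led by Ndufs4 (2.31) and Ndufc1 (2.23). Cytosolic ribosomal protein genes had a median of 0.51 (percentile 99.6). In KO minus WT they stood at 0.32 between the IgG-RIP arrays alone (percentile 100). Between the AGO2-RIP arrays alone they stood at -0.19 (percentile 31.8), so the difference lay mainly in the control. Macrophage markers had a median of 0.50 (percentile 97.9), with the mannose receptor gene Mrc1 (2.67) and Pf4 (1.52) highest, but of 0.01 over input (percentile 78.7), and between the IgG-RIP arrays alone they were 0.40 higher in KO (percentile 99.98). Fatty acid oxidation genes had a median of 0.63 (percentile 96.2), with Acsl1 (3.09) and Acadl (2.27) highest. In KO minus WT they stood at 0.42 between the IgG-RIP arrays alone (percentile 98.3). Between the AGO2-RIP arrays alone they stood at -0.25 (percentile 13.6), so much of the difference lay in the control. The targets of miR-155 (0.66, percentile 89.6), miR-223 (0.59, percentile 87.3), miR-21 (0.66, percentile 89.9), miR-17~92 (0.91, percentile 96.9) and miR-10a (0.81, percentile 93.9) lay within the range of random lists, as did those of miR-146a (-0.91, percentile 2.87). Nuclear non-coding RNAs had a median of -0.88 (percentile 0.77), with Rnu2-10 (-2.24) and Snhg1 (-1.73) lowest. In KO minus WT they stood at -0.41 between the IgG-RIP arrays alone (percentile 5.26). Between the AGO2-RIP arrays alone they stood at -0.02 (percentile 52.5). Alternative activation genes had a median of -0.72 (percentile 0.77, or 5.30 after the stretch), with Mgl2 (-1.34), Clec10a (-1.23) and 2 others at least 2-fold higher in KO and Mrc1 (2.67) and Stat6 (1.93) higher in WT. After the stretch mitochondrial ribosomal protein genes (percentile 99.97), respiratory chain genes (99.6), cytosolic ribosomal protein genes (99.99), macrophage markers (99.1) and nuclear non-coding RNAs (1.68) stayed outside the range of random lists, and glycolysis genes moved out of it (from 97.45 to 99.2). The stretch brings in only lists whose KO median lay clearly on the WT side of all genes. Less that of all genes, the KO median was -0.12 for cytosolic ribosomal protein genes, 0.03 for macrophage markers and -0.03 for glycolysis genes. For nuclear non-coding RNAs it was 0.31, against -0.37 in WT. For these lists the stretch thus decides nothing.

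**Figure D3:**
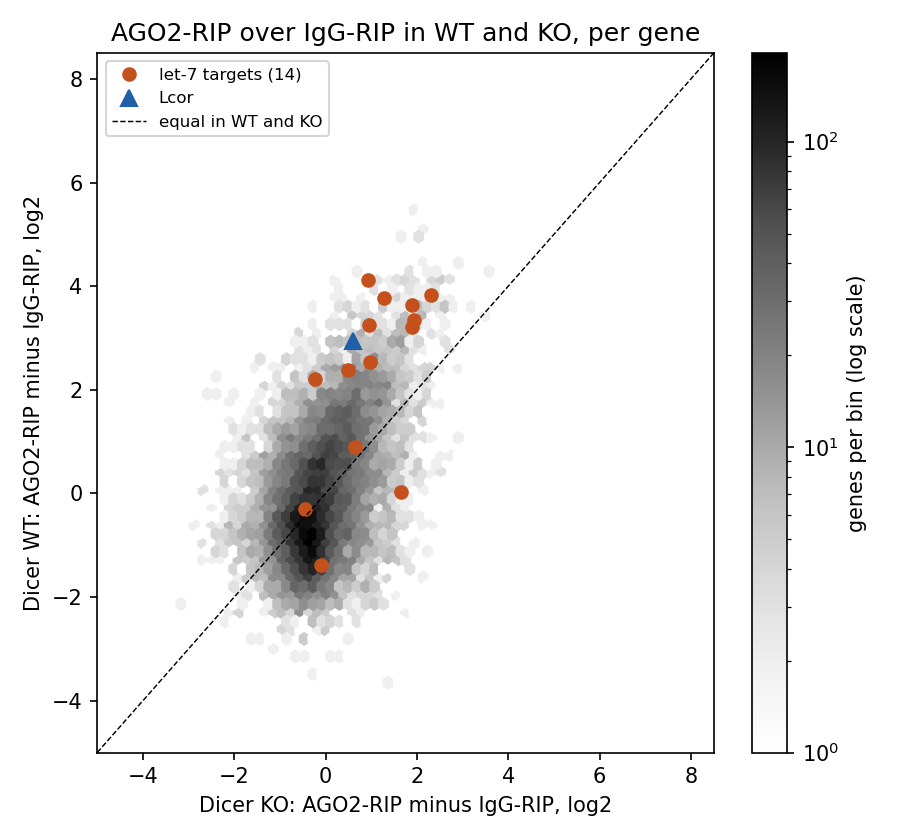
AGO2-RIP minus IgG-RIP (log2) in Dicer KO on the horizontal and Dicer WT on the vertical axis for 14054 genes, shown as hexagonal bins shaded on a log scale by the number of genes; 1 gene, Muc5b, lies outside the axes. Circles are the 14 measured let-7 targets, of which 12 lie above the dashed line of equal values, and the triangle is Lcor, at 2.94 in WT and 0.60 in KO.

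Taking input in place of IgG-RIP as the reference sets the precipitate against the starting RNA. The genes higher in WT were led by Mblac1 (3.45), Prrg1 (3.37), Mdfi (3.37), an inhibitor of myogenic transcription factors, the ciliary gene Iqcb1 (3.36), Ikzf2 (3.31), which encodes the transcription factor Helios, Rhobtb2 (3.30), the glycosyltransferase gene Mgat4b (3.21) and Fam78a (3.09). Those higher in KO were led by Slc32a1 (-5.86), whose input difference was -5.22, then Trip6 (-5.31), Mamld1 (-3.88), Spata5l1 (-3.45), Trappc5 (-3.24), a subunit of a vesicle tethering complex, the Integrator subunit gene Ints5 (-2.86), the ribonucleotide reductase gene Rrm2b (-2.85) and Srr (-2.72), a serine racemase. Another measured probe gave the opposite sign for Slc32a1, Trappc5 and Rrm2b. The Slc32a1 signal was high on the WT input array alone (4.83). On the KO AGO2-RIP array Rhobtb2 (-2.41), Mgat4b (-2.22) and Mdfi (-2.06) lay near the dimmest spot well above background (-2.54). On the WT AGO2-RIP array Trip6 (-2.43) lay near the dimmest such spot (-2.62). Ikzf2 (-0.78) and Fam78a (-0.54) lay further above it on KO AGO2-RIP. Of 13868 genes 1609 were at least 2-fold higher in WT and 968 in KO. The share higher in WT was 62.4%, against 48.2% with median centring (1242 and 1337), 77.5% with normexp (1049 and 304) and 39.7% with no filter (3817 and 5793).

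Let-7 targets had a median WT minus KO difference of 1.31 over input (percentile 100), with 9 of 13 at least 2-fold higher in WT and 0 in KO, led by Arid3b (2.87) and Arid3a (2.34). In KO minus WT they stood at 0.43 in input (percentile 100) and at -1.02 in AGO2-RIP (percentile 0.00). Part of the difference thus came from the input arrays. Lcor was 2.45 higher in WT, made up of a KO input 2.40 above WT and AGO2-RIP signals that differed by -0.05. The p53 targets had a median of 0.78 (percentile 99.9), led by Trp53inp1 (1.81) and the kinase gene Plk2 (1.48), and cell cycle genes of 0.48 (percentile 99.2), led by Ccne1 (1.31) and the replication helicase gene Mcm5 (1.16). Respiratory chain genes had a median of 0.30 (percentile 99.2). Cytosolic ribosomal protein genes (-0.37, percentile 0.10), replication-dependent histone genes (-0.40, percentile 0.50) and nuclear non-coding RNAs (-0.78, percentile 0.07) stood lower. In KO minus WT, cytosolic ribosomal protein genes stood at -0.52 in input (percentile 0.00) and -0.19 in AGO2-RIP (percentile 31.8). Nuclear non-coding RNAs stood at -0.71 (percentile 0.00) and -0.02 (percentile 52.5), so both differences lay mainly in the input arrays. Histone genes stood at -0.31 (percentile 3.2) and 0.10 (percentile 88.5). Over IgG-RIP the cytosolic ribosomal protein genes had the opposite sign (0.51). Mitochondrial ribosomal protein genes (0.21, percentile 84.6) and fatty acid oxidation genes (0.30, percentile 88.0) lay within the range of random lists. Over both references 837 of the 12385 genes above background on all arrays were at least 2-fold higher in WT, where independent lists would share 280. The references share the AGO2-RIP arrays. Across genes the differences correlated at 0.61 with a covariance of 0.54, and spot noise alone, simulated with the shared arrays, gave 0.45 and 0.04. Spot noise leaves out precipitation and amplification. The difference between the AGO2-RIP arrays enters both references, with an SD of 0.71 across these genes, and its square makes up most of the covariance. The excess of shared genes is thus no independent agreement between the references. Each group held 1 array, so genotype and noise within that shared difference could not be split.

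Macrophage markers were well above background for 29 of 30 genes on the WT input and for 30 of 30 on the KO input array. Their KO minus WT median was -0.03 (percentile 99.8), with Lyz1 (5.81) and Maf (0.71) highest and Cd14 (-0.89) and the galectin gene Lgals3 (-0.59) lowest. Of 16 neutrophil markers 5 were above background on each input array, with a median of -0.49 (percentile 3.46) and S100a9 (-1.42) lowest. Osteoclast markers were above background for 6 of 11 on each, with a median of -0.07 (percentile 74.1), Itgb3 (1.82) highest and Acp5 (-1.31) lowest. T and NK cell markers were above background for 5 of 17 on the WT and 8 of 17 on the KO input array, with a median of 0.19 (percentile 79.5) over 5 measured members. Few markers of B cells (2 of 13 in WT and 3 of 13 in KO), erythroid cells (2 of 14 in each), fibroblasts and stroma (2 of 17 and 3 of 17) and dendritic cells (3 of 12 and 4 of 12) were above background, too few for a median.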

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

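These genes are among the 8 at either end of the WT minus KO difference of AGO2-RIP over IgG-RIP and were past 2-fold in opposite directions in the genotypes; for each, the difference was not tested, since each group held 1 array. Lower than IgG-RIP in WT and higher in KO were D9Ertd115e (-4.21 in WT, 2.44 in KO, WT minus KO -6.65), Cxcr6 (-3.39, 2.08, -5.47), a chemokine receptor, D10Bwg1070e (-3.75, 1.38, -5.13), Ica1 (-2.07, 2.89, -4.96), an islet cell autoantigen, Mvp (-3.39, 1.33, -4.72), the major vault protein, Tent5a (-1.43, 3.28, -4.71) and Zfp108 (-2.07, 2.64, -4.71). Higher than IgG-RIP in WT and lower in KO were Kcna3 (3.67, -2.59, 6.26), a potassium channel, Wdtc1 (4.06, -1.99, 6.04), Bcs1l (2.14, -2.80, 4.94), an assembly factor of respiratory complexes, Ppp2r5d (3.01, -1.84, 4.86), Angptl6 (2.02, -2.61, 4.63) and Gtf2h2 (2.24, -2.36, 4.60). Among all 14054 genes 139 were higher in WT and lower in KO, where independent lists would share 264, and 134 were lower in WT and higher in KO, where independent lists would share 317. Picking genes by the size of that difference itself favours opposite signs. Another measured probe gave the opposite sign for Ppp2r5d, Gtf2h2 and Tent5a. The IgG-RIP arrays differed more than the AGO2-RIP arrays for all flagged genes but D10Bwg1070e, Zfp108 and Bcs1l. Mvp, for example, was 2.11 in WT and -1.64 in KO on IgG-RIP, against -1.28 and -0.31 on AGO2-RIP. Wdtc1, Ppp2r5d and Kcna3 on WT IgG-RIP, and Zfp108 and Ica1 on KO IgG-RIP, lay near the dimmest spot well above background.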

How the results depend on the processing

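With normexp, 1174 genes were at least 2-fold higher and 593 lower in AGO2-RIP than IgG-RIP in KO, 1420 were lower in WT, 51 were higher and 92 lower in KO input, 1078 had AGO2-RIP over IgG-RIP higher in KO, 1049 had AGO2-RIP over input higher in WT and 304 in KO, and limma called 248 higher and 15 lower. With only genes above background on all 6 arrays, 1381 were higher and 972 lower in the KO precipitate, 2198 were lower in WT, 107 were higher and 137 lower in KO input, and limma called 538 higher and 40 lower. Fewer genes enter by construction. There the miR-21 targets in KO stood at -0.0505 relative to the median of all genes. With no filter, 4098 genes were higher and 4278 lower in the KO precipitate, 7352 were lower in WT, 1391 were higher and 2169 lower in KO input, 6091 had AGO2-RIP over IgG-RIP higher in WT and 6978 in KO, 3817 had AGO2-RIP over input higher in WT and 5793 in KO, and 2208 were higher in WT over both references. Dim spots enter by construction. With no filter the miR-146a targets in WT stood 0.77 above the median of all genes, and the mitochondrial ribosomal protein genes stood 0.0804 above it in KO minus WT input. Of 97 values of named genes, 87 moved by more than spot noise with normexp, 52 with quantile normalization and 20 with median centring. With normexp Kcna3 was 3.96 in WT minus KO over IgG-RIP, Rhobtb2 1.52 and Mgat4b 1.54 in that over input, and Hyal1 (0.78), Bsn (0.80) and Mtap (-0.99) in input and Apoe in WT were no longer past 2-fold. With the median of a gene's probes, 61 values of named genes stayed within spot noise, 35 moved and 1 past 2-fold reversed, Tmem87a at 1.20. Ago2 over IgG-RIP, not past 2-fold, also changed sign, to 0.29 in WT and 0.51 in KO. Among the others moved were Ccdc28b (2.77), Mapk8ip3 (-1.55) and Cracr2b (-1.80) in WT, Gtf2h2 (1.43) and Lcor (1.06) in WT minus KO over IgG-RIP, and Atf7 (0.97) in input. With no genotype term limma called 134 higher and 12 lower. With each precipitate array left out of limma in turn, 0 to 459 genes were called higher and 0 to 67 lower, with 459 and 67 when the KO IgG-RIP array was left out, the lone array of a fraction being assumed to vary like the other groups. For the other changes the cause was not tested. Quantile normalization, median centring, the median of probes and the 4-array limma fit moved no count by more than 1.5 times. The seed site result and its alternatives were not run, and a slide term did not apply to 1 slide.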

Other observations

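Among the tests below, those of array-wide noise, of macrophage yield, of the KO IgG-RIP array alone and of a weaker KO contrast over input were chosen only after the result was seen. By the rules written beforehand, a shared lysozyme transcript and a linked strain would have been rejected and an enrichment without Dicer accepted. These rules could not decide the questions, for the reasons given below, so each is left open. Cytosolic ribosomal protein genes stood below input in both precipitates and both genotypes, with medians of -2.25 in WT and -1.93 in KO for AGO2-RIP and of -2.52 and -1.62 for IgG-RIP, each at percentile 0.00. Respiratory chain genes did too, at -1.21 and -1.32 for AGO2-RIP and -2.20 and -1.71 for IgG-RIP, so their excess over IgG-RIP reflects a control that held even less of them. Between the AGO2-RIP arrays alone, let-7 targets stood 1.02 lower in KO (percentile 0.00), with Nr6a1 (-2.29) and E2f5 (-1.74) lowest and Trim71 (0.36) among the highest, and inflammatory genes had a median of -0.70 (percentile 0.08).

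Lysozyme genes were far higher on the KO arrays: Lyz1 was 56.1-fold higher in KO input, 72.8-fold in AGO2-RIP and at least 174-fold in IgG-RIP, and Lyz2 at least 195-fold, at least 72.3-fold and 38.8-fold. Array-wide noise does not account for it, since only 1 other gene was 16-fold or more apart the same way in all 3 pairs. The macrophage marker median in KO minus WT input lay 0.05 above that of all genes, at percentile 99.8 of signal-matched lists. A shift of that size is too small for macrophage yield to account for the lysozymes. General markers do not test maturation. Whether 1 transcript was read by both probes could not be told apart, since the 21 of 60 bases they share do not show what else each binds and no fraction had both genes above background in both genotypes, nor could a linked stretch of another strain, with 3 of 94 genes within 10 Mb of Lyz2 past 2-fold in input, 1.16 times the share of all genes (95% interval 0.241 to 3.29). LysM-Cre is inserted in Lyz2, so a different number of Cre-carrying alleles in the genotypes may lower the WT signal, which the labels do not give and which was not tested. Exchanged genotype labels were not excluded either. Let-7 targets (0.43 in input, -1.02 in AGO2-RIP) went the way the labels say, though a weaker KO contrast stays open for the AGO2-RIP value. The Dicer1 probe (-0.77 in input, 0.01 in AGO2-RIP) may lie outside the deleted part and does not check the labels. The sex of the cells, which went with genotype against the labels, stays open for every such difference.

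Let-7 targets stood apart in the KO precipitate, where Dicer was to be absent. Matching random lists on probe GC left their percentile at 100.00, and input in place of IgG-RIP as the reference gave 99.98, which speaks against probe GC and against the KO IgG-RIP array alone. Remaining Dicer, long-lived miRNAs or an association with AGO2 that needs no miRNA may each leave such a signal, and none was tested. For the larger WT difference over IgG-RIP, stretching the KO values by 1.53 to the WT spread brought the percentile to 84.91, so a weaker contrast of the KO precipitates as a whole could explain that part. The same explanation stays open over input (1.31), where a stretch of 1.04 changed almost nothing (percentile 100.00) and decides nothing, and between the AGO2-RIP arrays alone (-1.02), where it was not tested and p53 targets (-0.67, percentile 0.58), cell cycle genes (-0.57, percentile 0.15) and mitochondrial ribosomal protein genes (-0.48, percentile 0.08) were lower in KO too.

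Genes at least 2-fold higher in KO input were also those with more AGO2-RIP signal over IgG-RIP in WT, arrays that share nothing with the inputs, with the 111 measured at percentile 99.84, and in KO the 135 measured lay 0.58 above all genes (percentile 100). Their excess over all genes in WT less that in KO was -0.02, but over different genes (111 and 135), and the 107 genes measured on all 4 arrays had a WT minus KO median 0.27 above that of all genes (percentile 97.6), so the enrichment was present in KO, and whether part of it needs Dicer cannot be told apart. Genes at least 2-fold lower in KO input stood at percentile 99.8 as well. Release from miRNA control was not tested.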
